A study of Arabidopsis thaliana with 6 samples.

How the data were processed

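Whole seedlings of Arabidopsis thaliana, wild type of the Col-0 accession, were profiled on 6 Affymetrix expression arrays, 3 of dark-grown controls and 3 of dark-grown seedlings with rifampicin in the agar. Per the labels' protocols, total RNA was extracted with a column kit that includes a DNase step and was amplified and biotin-labelled with a whole-transcript kit. Per the submitters' processing notes, the authors summarised the arrays with RMA, and the deposited table holds log2 values for 38408 rows and 6 columns. The version of RMA, the genome build of the annotation and whether all 6 arrays were normalized together are not given in the sources used here. No further normalization was applied before the main test.

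Rows were named through the platform annotation, which pairs 16722 rows with 1 gene symbol and 759 rows with several, and names 20927 rows not at all in the table used here. Of the 1-gene rows, 16574 were matched by gene number to the RefSeq gene table of assembly TAIR10.1, and 148 were not and kept the name in the annotation. That table served for names and locus codes, and no coordinates were taken from it. Where neighbouring genes were sought, genes were ordered by locus code. For the 148 genes with several rows, the row with the highest mean over all 6 arrays was used. This left 16548 genes, of which 16442 were nuclear, 63 plastid-encoded, 12 mitochondrion-encoded and 31 of a genome that the names did not settle. Most names (14743) were locus codes. With this naming, 120 of the 446 listed members of the fixed gene lists were measured, and 62 of 373 in the nuclear lists.

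The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, 2-sided), with Benjamini-Hochberg adjustment over all 16548 genes and an adjusted p threshold of 0.05. Gene lists with at least 3 measured members were tested with camera from limma at a preset correlation of 0.01, adjusted over the 16 lists tested. The estimated-correlation form of camera and fry were run as alternatives. Organelle-encoded genes were compared with nuclear genes among the changed genes by Fisher's exact test, 2-sided. Array means of a list were compared by an exact permutation test, which with 3 arrays against 3 cannot give a 2-sided p below 0.1. Changes are log2 differences, rifampicin minus control, with the moderated standard error (SE), and group levels are given as mean ± SD over 3 arrays.

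Control samples were assigned to the dark group by their titles and source names, since their treatment text covers light as well as darkness. The groups, the tests, the 28 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 8 largest rises and the 8 largest falls among changed genes whose replicates did not overlap. From each list it took up to 2 risen and 2 fallen members, or the member with the largest absolute change where none passed. It also always named AOX1A, AOX1D, RPOTp, RPOTmp, RPOTm, GUN1, HY5, psbA, rbcL, psaA, rpoB, accD, LHCB1.2 and RBCS1A. Of these, AOX1A, AOX1D, RPOTp, RPOTm, GUN1, HY5, LHCB1.2 and RBCS1A were not analysed here because no row with a single name carries them. The lists of plastid transfer and ribosomal RNAs, carotenoid synthesis, salicylate and defence, and seed storage had no measured member.

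Alternatives were quantile, median and cyclic loess scaling of the deposited columns, removal of the dimmest 25% or 50% of the genes, every row of the table, nuclear genes only, a variance prior that depends on intensity, a robust prior, array quality weights, the replicate number as a block, each replicate left out, and other thresholds. List results under an alternative were compared by the sign of the median. Camera's own direction differed from the main result in 16 of 278 such comparisons, all of lists that did not pass in either. The sign of the median was adopted as the criterion after these comparisons had been seen.

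The procedure was tested on simulated data for the 16548 genes of this comparison, with 200 genes changed in each of 5 simulations. It recovered 88.8% of changes of log2 size 1 and 99.8% of changes of size 2, and 7.46% of the calls were false. The simulated noise was normal, independent between genes and drawn with variances that limma had already moderated. Recovery in the real arrays can therefore be lower, and a gene not called need not be unchanged. There AT2G07738 (2.20) and AT2G07691 (2.07) missed the threshold in limma (adjusted p = 0.11 for both). The number of arrays limits the precision. Genes with near-identical copies, including the genes of the mitochondrial insertion on chromosome 2, can share hybridisation signal, so their rows cannot be assigned to 1 copy. The insertion was defined by locus codes, from the first to the last AT2G07 code that shares a row with a mitochondrial gene. It held 43 tested nuclear genes. No coordinates or sequences were used, so the 43 can include genes that are not copies of mitochondrial sequence.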

Results

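The data comprised 6 whole-transcript arrays of whole wild-type seedlings that had spent 4 days in darkness, before true leaves form. Seeds were chilled for 72 h, given 6 h of light to start germination and kept at 21 °C on agar with 1% sucrose. The control group and the rifampicin group each held 3 biological replicates, and the rifampicin group grew with 200 µg/ml of the drug in the agar. Rifampicin is an antibiotic that blocks bacterial-type RNA polymerases, a class that in plants includes the plastid-encoded RNA polymerase. The titles and source names of the control samples give darkness, but their treatment text describes growth in continuous light as well as in darkness. The controls were taken as dark-grown from their titles, and each difference below rests on that reading. The comparison asked which transcripts of dark-grown seedlings differ in level when this drug is present.

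The arrays were alike in their distributions, with medians between 5.03 and 5.10 on the log2 scale. Pairs of control arrays correlated at 0.974 to 0.982, pairs of rifampicin arrays at 0.980 to 0.983 and pairs across the groups at 0.973 to 0.978. These correlations are over all 38408 rows, which are not independent replicates. The leading principal component took 40.2% of the variance and separated the groups. The sample records of the controls and of the rifampicin seedlings carry numbers from separate blocks far apart, the controls' being the lower. The labels give no array batch, so array handling or growth that differed between these sets cannot be told apart from the treatment.

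The largest rise with rifampicin was that of AT5G09570, which encodes the mitochondrial cysteine-motif protein AT12CYS-2. Its level went from 3.44 ± 0.24 in controls to 7.89 ± 0.63 with rifampicin (SD, n = 3), a change of 4.45 (SE 0.29, adjusted p = 0.0041), or 21.9-fold. NDB4, an alternative NAD(P)H dehydrogenase of the mitochondrial inner membrane, rose by 2.89 (SE 0.28, adjusted p = 0.013), and the glutathione transferase gene GSTU25 rose by 2.33 (SE 0.41, adjusted p = 0.044). The other genes among the 8 largest rises were AT5G54560 (3.04), AT5G54450 (2.89), AT5G52940 (2.82), AT1G55990 (2.59) and AT5G13900 (2.29), with adjusted p-values from 0.013 to 0.044. Control means of AT5G52940 (1.78), AT1G55990 (2.96) and GSTU25 (3.17) lay below the lower quartiles of the control arrays (3.29 to 3.37), with AT5G09570 just above. Background signal was not measured, so the sizes of rises from such low levels are uncertain.

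The largest fall was that of AT3G05640, a protein phosphatase 2C gene also called EGR1, which changed by -2.62 (SE 0.33, adjusted p = 0.021). AT1G15010 changed by -2.52 (SE 0.35), AT4G18280 by -2.12 and AT1G78230 by -2.05. The aspartyl protease family genes AT5G45120 and AT1G44130 changed by -2.21 and -1.91. AT2G23120, of the late embryogenesis abundant type, changed by -1.90, and AT5G66650, which encodes a chloroplast calcium uniporter, by -1.88. The adjusted p-values of these 8 falls lay between 0.016 and 0.030.

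**Figure D1:**
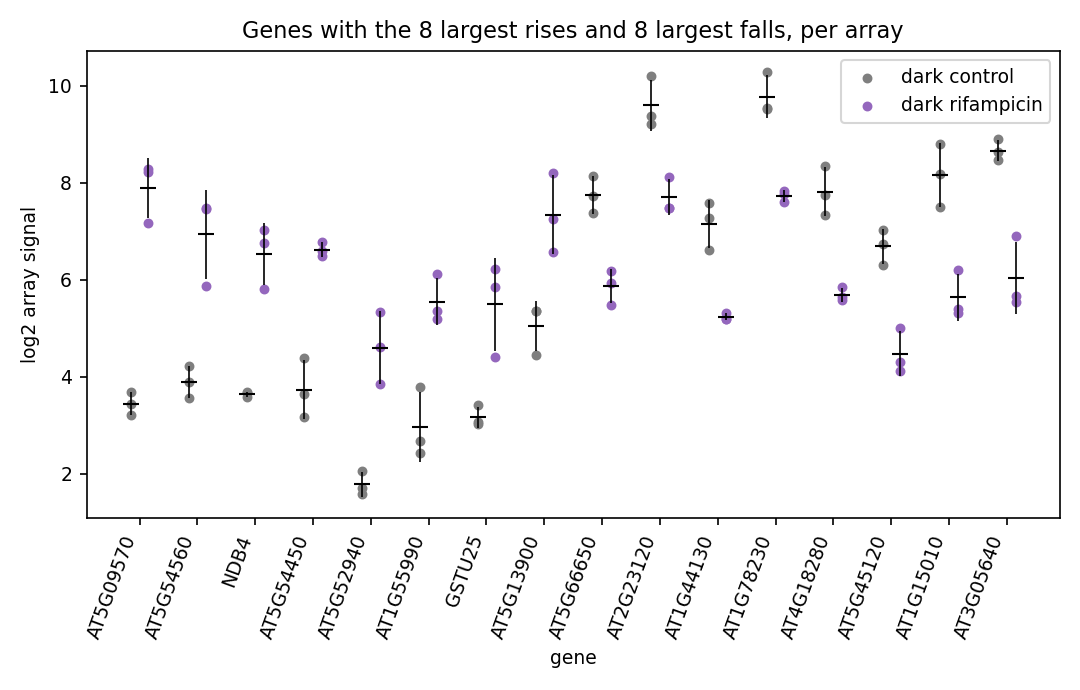
Log2 array signal of each array (points) with mean and SD (bars, n = 3) for the genes with the 8 largest rises and 8 largest falls, controls in grey and rifampicin in purple. The groups do not overlap in any of these genes, and AT5G09570 lies near 3.44 in controls and 7.89 with rifampicin.

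In total 173 of 16548 genes changed, 94 higher and 79 lower with rifampicin, and 103 of them by at least 1 log2 unit (54 higher, 49 lower). All 173 had replicates that did not overlap between the groups, as did 22.4% of all genes, where chance gives 10%. The smallest absolute change called was 0.63 and the median was 1.06. At an unadjusted p of 0.05, 2696 genes passed, and 2 genes passed at an adjusted p of 0.01, AT5G09570 and AT1G24095 (1.73, SE 0.13), the latter chosen after its values were seen. The number of calls was lower with any 1 array left out: it was 0 without rifampicin replicate 3 (1993 genes at an unadjusted p of 0.05), 20 without control replicate 1, 20 without control replicate 2, 29 without rifampicin replicate 2, 86 without control replicate 3 and 164 without rifampicin replicate 1. These fits have equal numbers of arrays, so the count depended on which array was removed. The loss of calls through fewer arrays alone was not separated from this. With every row of the table tested together the number of calls was 13. AT5G09570 passed in 16 of 17 alternative settings, with adjusted p-values from 2.4e-04 upward, and missed at 0.0504 without rifampicin replicate 3.

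Measured genes of the mitochondrial retrograde response, a nuclear programme induced when mitochondrial function is disturbed, were higher as a group. Only 6 of the 22 listed members were measured, without AOX1A and AOX1D. Of these 6, 4 rose: AT5G09570, NDB4, GSTU25 and AT2G21640. The last, the oxidative stress gene UPOX, rose by 2.04 (SE 0.27, adjusted p = 0.024) and was named after its values were seen. The remaining members were AT5G51440, encoding the mitochondrial small heat shock protein HSP23.5 (1.08, adjusted p = 0.0504), and NDB2 (0.27, adjusted p = 0.37). Adjusted over the list alone, 5 rose and none fell. The median change was 2.18, and camera gave an adjusted p of 1.8e-09. The adjusted p was 0.49 with an estimated correlation and 0.039 by fry. Mean levels of the list went from 4.96 ± 0.03 to 7.14 ± 0.54 (SD, n = 3), with an exact permutation p of 0.1, the smallest that 3 against 3 arrays can give.

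The xenobiotic detoxification list and the alternative respiration list shared members with it. Among 6 measured of 34 listed detoxification genes, 2 rose, GSTU25 and GSTU22 (2.15-fold, adjusted p = 0.049), and 4 rose adjusted over the list alone. Both calls over all genes ended with quantile scaling (adjusted p = 0.054 and 0.053), with every row tested (both 0.11), with the replicate number as a block (0.083 and 0.086) and without any 1 array other than rifampicin replicate 1 (0.087 to 0.19), and that of GSTU22 also with median centring (0.052) and the robust prior (0.051). The median of the 6 was 1.01, with a camera adjusted p of 5.1e-05 and an adjusted p of 0.49 with an estimated correlation. Among 4 measured of 14 listed alternative respiration genes, NDB4 alone rose, over all genes and adjusted over the list alone. That list had a median of 0.33 and an adjusted p of 0.018, or 0.060 without control replicate 2, and its median ran from 0.18 to 0.60 with each array left out. It had an adjusted p of 0.49 with an estimated correlation.

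None of the 63 plastid-encoded genes passed limma's test, over all genes or adjusted over the list alone, although 60 of them had values below 0 and 15 of these had an unadjusted p under 0.05. Their median change was -0.25, and camera gave an adjusted p of 5.4e-08, against an adjusted p of 0.51 with an estimated correlation and 0.18 by fry. The mean over these genes was 12.31 ± 0.22 in controls and 12.05 ± 0.11 with rifampicin (SD, n = 3), with an exact permutation p of 0.2. The median was -0.14 without control replicate 3 and -0.38 without control replicate 2. Values were 0.01 for psbA of photosystem II (adjusted p = 0.99), -0.06 for rbcL, the large subunit of Rubisco (adjusted p = 0.84), and -0.36 for psaA of photosystem I (adjusted p = 0.24). The control means of psbA and rbcL were 13.55 and 13.49, against array maxima of 14.18 to 14.27. Compressed signal was not tested at such levels, so values near 0 there need not mean unchanged RNA. The same limit holds for the median change of the 63 genes, whose median level was 12.46. The polymerase subunit gene rpoB had -0.26 and the fatty acid synthesis gene accD -0.44 (adjusted p = 0.60 and 0.30), and the lowest value was that of rpl36 (-0.62, adjusted p = 0.36). With an array left out rpoB ran from -0.42 (without control replicate 2) to -0.059 (without control replicate 3), accD from -0.59 to -0.25 (the same arrays) and rpl36 from -0.88 to -0.37.

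Split by function, no plastid list had a member past the threshold, over all genes or adjusted over the list alone. The 10 genes of the NDH complex had a median of -0.35 (camera adjusted p = 7.0e-04; ndhI -0.59), and the 25 photosystem, cytochrome and Rubisco genes -0.15 (adjusted p = 9.2e-04; psbT -0.37), or -0.28 with cyclic loess scaling. The 13 ribosomal protein genes had -0.31 (adjusted p = 0.0044), which became -0.16 without control replicate 3 (adjusted p = 0.25) and -0.51 without control replicate 2. The 6 genes with promoters for the nuclear-type polymerase had -0.23 (adjusted p = 0.044). The 4 ATP synthase genes had -0.19 (adjusted p = 0.12; atpI -0.29), with -0.13 without control replicate 3 or rifampicin replicate 1 (adjusted p = 0.32 and 0.36), but -0.31 with cyclic loess scaling, where the list passed (adjusted p = 0.0086). With an estimated correlation these 5 lists had adjusted p-values from 0.49 to 0.51. The call of the nuclear-type promoter list ended without control replicate 1 (adjusted p = 0.052), control replicate 3 (-0.091, adjusted p = 0.32) or rifampicin replicate 1 (-0.094, adjusted p = 0.33), and its median was -0.39 without control replicate 2. It also ended with columns centred on their medians (0.053), without the dimmest 25% (0.077) or 50% (0.11) of the genes, and with array quality weights (0.073).

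No mitochondrion-encoded gene passed limma's test among 12, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their median was 0.11 (0.0013 with cyclic loess scaling), with a camera adjusted p of 0.12 (0.043 without rifampicin replicate 1 and 0.040 with the intensity-dependent prior), and the largest change was that of matR (0.31, adjusted p = 0.42). With 0 organelle genes changed, Fisher's exact test gave p = 1 for each genome and direction. So few nuclear genes changed that a count of 0 could not show under-representation. Of the 94 risen genes, 10 had locus codes in the range taken for the part of chromosome 2 that holds a copy of the mitochondrial genome. Their rows can share signal with mitochondrial RNA.

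**Figure D2:**
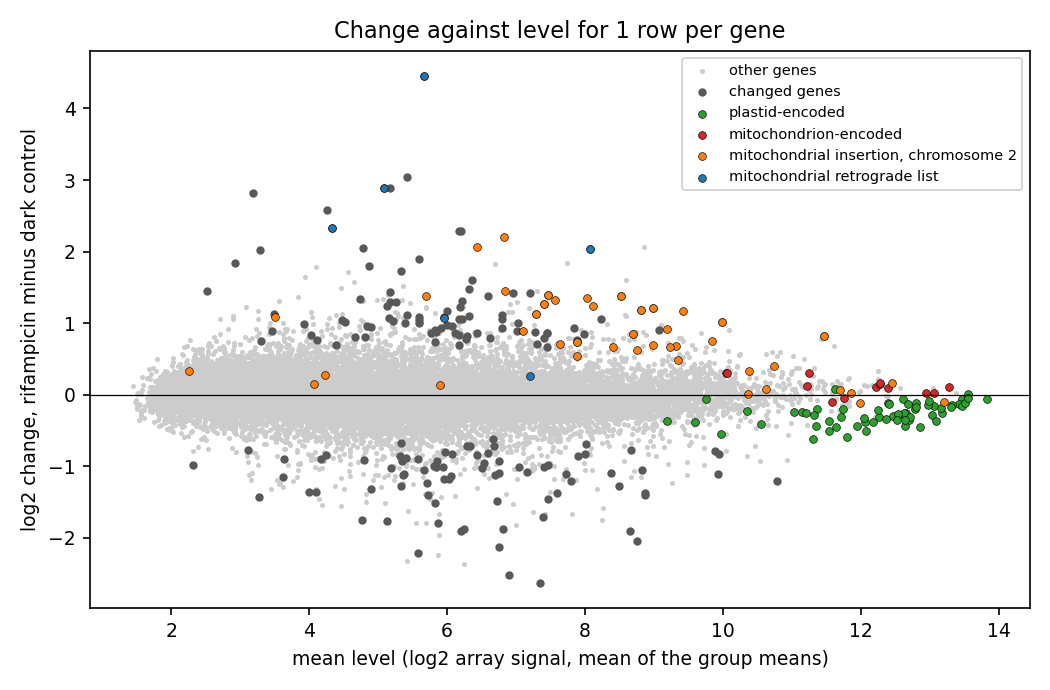
Log2 change (rifampicin minus control) against mean log2 signal for 16548 genes, with changed genes and 4 gene groups coloured. Plastid-encoded genes lie slightly below 0 at high levels (median -0.25), the retrograde list lies high (median 2.18), and genes of the mitochondrial insertion lie above 0 (median 0.74).

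The 7 measured nuclear genes for plastid ribosomal proteins (of 36 listed) all had values above 0 as deposited. Their median was 0.31 and none passed the threshold, over all genes or adjusted over the list alone. Their largest value was 0.38 for AT3G13120, encoding PRPS10, and camera gave an adjusted p of 0.0031, with an adjusted p of 0.49 with an estimated correlation. The 6 measured chlorophyll and tetrapyrrole synthesis genes (of 28 listed) also all had values above 0 as deposited. Their median was 0.25, with none past either threshold and HEME1 at 0.52. Camera gave that list an adjusted p of 0.038, with 0.49 as the adjusted p with an estimated correlation. Its adjusted p was 0.052 without control replicate 1, 0.15 without control replicate 2, 0.064 without rifampicin replicate 1 and 0.063 without rifampicin replicate 2, and 0.070 with quantile and 0.056 with cyclic loess scaling.

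The 7 measured nuclear photosynthesis genes (of 42 listed) had a median of 0.13, a mean of -0.06 and a downward camera direction (adjusted p = 0.98). The signs thus differ. Their largest value was -0.75 for the light-harvesting gene LHB1B2 (adjusted p = 0.19). AT5G15700, encoding the organelle RNA polymerase RPOTmp and the only measured member of its list, had 0.55 (SE 0.13). It missed the threshold over all genes (adjusted p = 0.092) and passed, as 1 gene, adjusted over the list alone.

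Among the stress lists, the 3 measured heat shock genes (of 19 listed) had a median of 0.54 (camera adjusted p = 0.038). They were led by AT5G51440, the 1 member past the threshold adjusted over the list alone. AT5G51440 is also in the retrograde list, so these lists are not separate evidence. The adjusted p of the heat shock list was 0.49 with an estimated correlation. The call ended without control replicate 1 (adjusted p = 0.052), control replicate 2 (0.060), control replicate 3 (0.066) or rifampicin replicate 1 (0.064), and the median was 0.28 without rifampicin replicate 3. KIN1, a cold- and drought-responsive gene, had -0.96 (adjusted p = 0.088) and fell adjusted over the list alone, as 1 of 2 abscisic acid and drought genes.

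No member passed either threshold in the remaining lists. The 6 measured cell elongation genes (of 26 listed) had a median of -0.04 and an upward camera direction (adjusted p = 0.77), with XTH20 at -0.73. The 3 measured root tissue markers (of 11 listed) had a median of -0.003 and an upward camera direction (adjusted p = 0.98), with EXPA7 at -0.14. Lists with fewer than 3 measured members were not tested as lists. Their leading members were HYH of light signalling (0.46), DFR of flavonoid synthesis (0.56), AT3G10040 of the hypoxia list (0.09), PDF1.2 of the jasmonate list (0.39), SDP1 of seed reserve mobilisation (-0.36) and AUR1 of the mitotic cell cycle (-0.34). With an array left out HYH ran from 0.10 to 0.74, DFR from 0.18 to 0.86, PDF1.2 from 0.23 to 0.54 and XTH20 from -1.06 to -0.38.

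**Figure D3:**
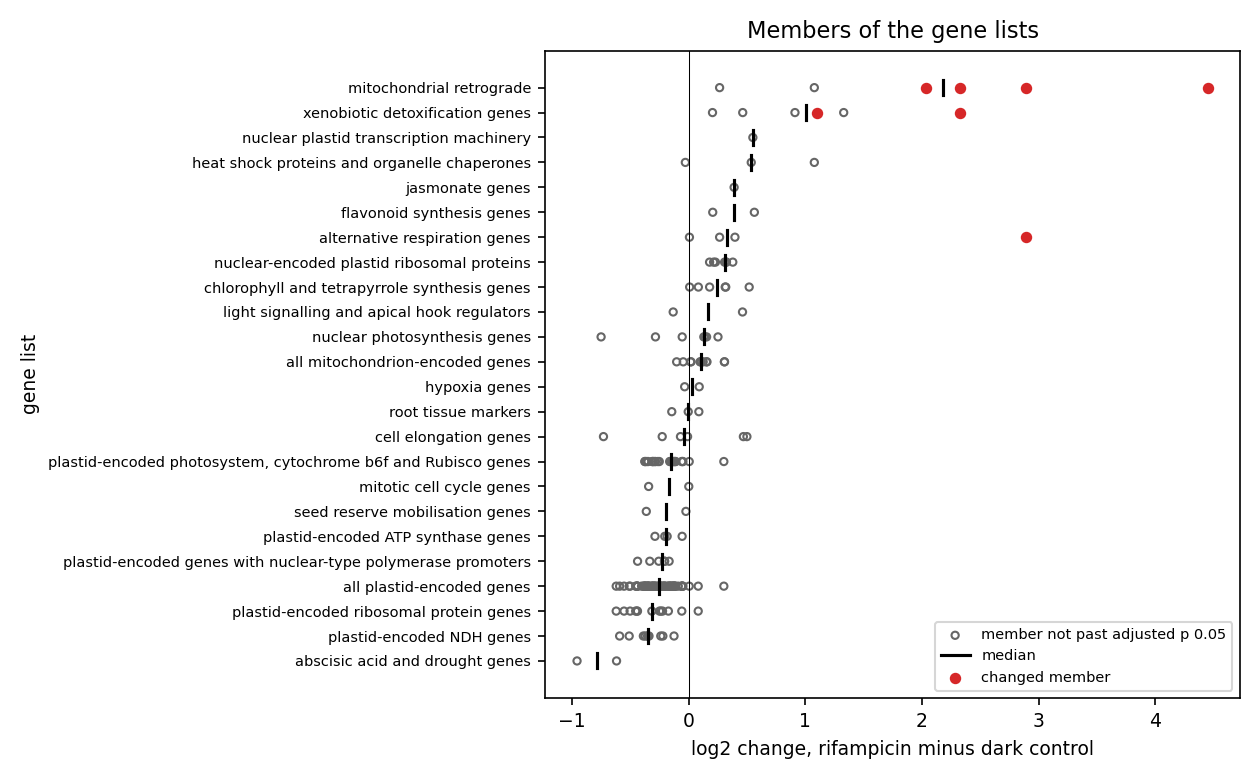
Log2 change of each measured member of the gene lists, with changed members in red, others as open circles and the median of each list as a bar. Changed members occur in the mitochondrial retrograde list (4 of 6), the xenobiotic list (2 of 6) and the alternative respiration list (1 of 4).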

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

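The tests of scale, of batches, of added DNA, of an equal mitochondrial rise, of compression at levels of 11 or more, of a level trend in the plastid genes and of their spread between controls were chosen after the results were seen, and the genes of the mitochondrial insertion were singled out after their values were seen. Rows with no gene name in the annotation were tested only where all 38408 rows were tested together, and there 11 of those 20927 rows passed limma at an adjusted p of 0.05, all higher with rifampicin. Their log2 changes reached 3.86, and they hold 9 distinct sets of values because some rows repeat. At an unadjusted p of 0.05, 1559 unnamed rows were higher and 1522 lower, or 14.7% of them. In that same fit of all rows, 13.5% of the 16548 genes of the main test passed (1067 higher, 1162 lower). In the main fit, with its own variance prior, 2696 of these genes passed. The unnamed rows were not part of that fit.

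Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, reached the 173 changed genes, and the highest of the other splits gave 0. For gene lists, likewise 1 split reached the real value of 11, and the highest other gave 8, so at the preset correlation lists also passed in splits that do not follow the groups. With 10 splits no share under 0.05 can be reached. The lowest quantile gap between arrays of different groups, 0.0192, was below the highest gap inside a group (0.0359). The highest gap between groups, 0.0436, was above it, so the gaps do not decide whether the groups were left on different scales. With quantile scaling, which makes the 6 distributions equal, 163 of the 173 calls remained. This argues against a difference of scale as the source of most calls. Shifts of single genes from separate normalization stay open. The labels name 0 batches that hold arrays of both groups, so arrays of the 2 groups prepared or scanned apart could account for changes and cannot be told apart from the drug.

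Genes assigned by locus code to the mitochondrial insertion of chromosome 2 mostly lay higher with rifampicin. Of the 43, 41 were above 0 with a median of 0.74, 10 rose, and none fell. The 10 with a mean of 10 or more had a median of 0.07 (median level 11.6). This was close to the 0.11 (SD 0.12) of the mitochondrion-encoded genes (median level 12.2). However, 1 of these 10, AT2G07722, rose by 0.83 (level 11.5, limma adjusted p = 0.045), and AT2G07689 and AT2G07719 had 0.41 and 0.33. The array mean of the 43 went from 8.08 ± 0.04 to 8.87 ± 0.14 (SD, n = 3), and the median stayed between 0.69 and 0.82 with each array left out. An equal rise of the array signal of all mitochondrial RNA is argued against by the median of 0.11 of the mitochondrion-encoded genes and by that of the bright insertion genes, AT2G07722 excepted, as far as their signal was not compressed. Compressed signal was examined through the spread of the changes of nuclear genes. A band that starts at 10 and leaves out the brightest 2 held 289 genes with a median level of 10.5. Their changes spread 0.824 times as widely as in 5026 genes with means of 6 to 9. For the 73 nuclear genes at 11 or more (median level 11.5) the ratio was 0.741. Its 95% bootstrap interval ran from 0.456 to 0.929, which reaches below 0.5. Of the 289 genes 0 rose and 1 fell, and of the 5026 genes 38 rose and 41 fell. The spreads thus largely reflect variation between arrays and cannot show how far a true change is shrunk, so compression stays open at both levels. DNA left in the rifampicin RNA stays open, since plastid-encoded genes at levels of 9 to 11 had a median of -0.37, where added DNA would raise them but a fall of plastid RNA could hide it; a drug effect on weakly transcribed mitochondrial sequence stays open as well.

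The plastid-encoded genes lay lower with rifampicin, with a median of -0.25. A trend of the array signal with level is argued against for the 28 plastid genes in the level range of those 289 nuclear genes: their median was -0.31 at a median level of 11.7, and of 10000 nuclear lists with a gene within 0.25 of the level of each plastid gene (median level 11.7, median change 0.05) none lay as low, the lowest being -0.115, nor did any of 10000 random lists from all 289 (median 0.0074 at 10.5, lowest -0.192), so that each share is put at 1e-04, the least that 10000 lists can give. The lists drew nuclear genes independently, whereas the 63 plastid genes moved together (estimated correlation 0.56). Neither share is therefore a p-value for the fall of the plastid genes. Above that range there were 31 plastid and 2 nuclear genes, so level was not tested there. The spread between control arrays could account for the difference, since the plastid mean ranged over 0.444 among the 3 controls, more than the group difference of -0.26. A drug effect on plastid transcription stays open and was not separated from it.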

How the results depend on the processing

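The counts of changed genes moved most, and the cause was not tested beyond what the settings change by construction (genes tested, arrays, thresholds). Against 173 (94 higher, 79 lower), the count was 421 (209 and 212) without the dimmer 50% of the genes, 13 (13 and 0) with every row of the table, 349 (181 and 168) with the intensity-dependent prior, 535 (274 and 261) with array quality weights, 103 (54 and 49) with a log2 minimum of 1 and 2 (2 and 0) at an adjusted p of 0.01. With the replicate number as a block it was 39 (21 and 18), of which 31 were among the 173. The numbers do not pair the samples: same-numbered arrays correlated at 0.094, -0.038 and 0.151 in their deviations. Array 3 alone of each group correlated best with its own number. With each array left out the count ran from 0 to 164, the higher genes from 0 to 92 and the lower genes from 0 to 72. The 3 scalings gave 165 to 179. The 11 lists past the threshold became 0 with an estimated correlation and 1 with fry, and 8 to 11 with an array left out. With nuclear genes only there were 6, because that setting removes the lists of plastid-encoded genes, and no nuclear list lost its call there.

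The retrograde list (median 2.18) lost its call with an estimated correlation (2.18, adjusted p = 0.49), and the plastid list (-0.25) with an estimated correlation (-0.25, adjusted p = 0.51) and fry (-0.25, adjusted p = 0.18). Organelle genes among changed genes stayed at 0 in each setting. All 17 named genes that had changed kept their sign, and they passed in 7 to 16 of up to 17 settings each. Signs turned for some values that passed in no setting. The value of psbA became -0.12 with cyclic loess. With an array left out psbA ran from -0.014 to 0.026, EXPA7 from -0.33 to 0.029, psbT from -0.79 to 0.035 and AT3G10040 from -0.0042 to 0.19. Without a turn of sign, HEME1 ran from 0.29 to 0.66, ndhI from -0.82 to -0.38, atpI from -0.39 to -0.15 and matR from 0.20 to 0.48, and rbcL became -0.19 with cyclic loess and -0.022 with quantile scaling. The root marker median became 0.013 with quantile and 0.012 with median scaling and ran from -0.33 to 0.10 with an array left out. The elongation median became 0.47 without the dimmer genes and ran from -0.13 to 0.056, and the nuclear photosynthesis median ran from -0.039 to 0.21. The robust prior leaves camera as it is and gave no list value.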

Other observations

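The genes named here, the look at the insertion genes by level and scaling and the test of risen neighbours were chosen after the results were seen. Fallen genes outside the naming rule included COR47 at -1.40 (SE 0.23, adjusted p = 0.039), KIN2 at -1.21 (SE 0.19, adjusted p = 0.035) and SRC2 at -1.18 (SE 0.19, adjusted p = 0.037), for which no enrichment was tested. The calmodulin-like gene CML38 had -1.76, the ubiquitin ligase gene PUB19 -1.43 and the sugar transporter gene SWEET3 -1.02. Among the risen genes, AT2G18193, AT4G36580 and AT3G03060, which encode ATPases of the AAA type, had 2.29, 1.44 and 1.37 (adjusted p = 0.013, 0.034 and 0.019), and CRR22, a plastid RNA editing factor, had 0.74 (adjusted p = 0.040).

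The median change of the genes of the mitochondrial insertion was smaller in the brighter of the bands below, which was not tested. The 26 with a mean below 9 had a median change of 1.11, and the 10 with a mean of 10 or more had 0.07. The dimmest genes did not follow this order. AT2G07640, AT2G07760, AT2G07750 and AT2G07695 (means from 2.26 to 5.89) had 0.34, 0.15, 0.27 and 0.13. In that range AT2G07673 and AT2G07692 had 1.09 and 1.38. The 11 with a mean of 9 to 11, a band that overlaps the last, had 0.67, all above 0. Compressed signal stays open for the brighter genes. The median of all 43 was 0.73, 0.76 and 0.74 under quantile, median and cyclic loess scaling.

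Some risen genes neighboured each other on chromosome 5, which could come from shared regulation or from similar sequence on the array. Outside the insertion there were 2 adjacent pairs among 84 risen genes in the order of locus codes, against 0.43 by chance. They were AT5G52930 (2.03) with AT5G52940 (2.82) and AT5G54550 (1.83) with AT5G54560 (3.04). Only tested nuclear genes were ordered, so untested genes can lie between the members of a pair. The permutation p was 0.063, so an excess was not shown. The 79 fallen genes made 0 pairs, with a permutation p of 1.

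None of 32 gene families of 8 or more members with a shared symbol moved as a set in camera, with 0 families past an adjusted p of 0.05 with an estimated correlation (lowest 0.58) and 0 with the preset correlation. The 14743 of 16548 genes named by a locus code could not enter a family, so families without a shared symbol were not tested.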
